A study of Mus musculus with 6 samples.

How the data were processed

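RNA-seq of total RNA was available for 6 samples of sorted mouse spleen CD4 T cells, 3 groups of 2. Per the labels, reads came from a NovaSeq instrument and were aligned to GRCm38, and the submitters' processing notes name R 3.6.2 and edgeR. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. The deposited table holds raw counts per gene for the 6 libraries, whole numbers with no normalization. Its 5 summary rows, for reads with no feature, ambiguous reads, low alignment quality, no alignment and more than 1 alignment, were kept out of library sizes and tests. Between 41169763 and 50779120 reads stood in the table per library, of which 33.7% to 46.9% were assigned to genes and 9.34% to 24.3% did not align. Because strand use is not stated, reads of overlapping antisense genes may be counted together, and genes with near-identical copies are uncertain. Between 24210 and 33138 genes had a count per library, and genes with few counts carry wide counting errors.

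Gene identifiers were looked up in GENCODE mouse release 21 on GRCm38. Of 47729 identifiers 47310 matched and 419 did not. Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total count 15), which left 15780. Library sizes were scaled by TMM. Counts were tested with edgeR's quasi-likelihood test (robust, current method), with all 6 libraries in 1 fit without an intercept and 3 residual degrees of freedom, and adjusted by Benjamini-Hochberg; an adjusted p under 0.05 was called. Log2 fold changes are given with their SE, and CPM are TMM-scaled with the SD of 2 libraries. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, statmod 1.5.0 and blastn 2.17.0.

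The groups, the 3 comparisons, the tests, the rule for named genes, 48 gene lists (912 genes, 6 not found in the table) and most alternatives were fixed before the data were examined. Lists covered T cell states and lineages, signalling, metabolism, stress and markers of other cell types. Of the 48 lists 45 had at least 3 tested members and were tested with camera at a preset correlation of 0.01; alternatives were an estimated correlation and fry. A list is said to rise or fall where camera called it, and no list was called in any comparison with an estimated correlation, for which the adjusted p is printed beside each. Named genes were, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean CPM of at least 5 and groups that did not overlap, leaving out unnamed gene models, immunoglobulin and T cell receptor segments, haemoglobins and mitochondrial genes; up to 4 members of smallest p of each called list; a fixed set of Notch, maturation and sort marker genes; the most abundant member of each cell marker list; and Xist with Y-linked genes. Il10 and Maf between OFF and ON and the pseudogene Rbpj-ps3 were named outside this rule, after their values were seen.

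The steps were tested on simulated counts drawn from the means of these libraries, with 200 genes changed in each of 5 runs. A log2 fold change of 1 was recovered for 64.2% of genes between OFF and ON, 62.2% between ON and WT and 61.0% between OFF and WT, and of 2 for 91.6%, 93.2% and 91.0%. False calls made up 9.94%, 10.7% and 8.98% of calls, above the nominal rate. Of 100 unchanged lists per comparison camera called 0, the estimated correlation 0, and fry 1, 0 and 1. These lists were random genes drawn independently, so they cannot show false calls that arise from correlated members. Between OFF and ON the estimated correlation was 0.825 in the proliferation list and -0.0715 in the Notch target list, against the preset 0.01. Replicates of each group differed by more than sampling noise, with chi-square per degree of freedom of 9.90 in WT, 69.5 in ON and 20.1 in OFF. Ratios of genes with 1 to 3 counts in a group have 95% counting intervals, and a group with 0 counts was set at a floor of 3 counts over the group.

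Overlaps and covariances of comparisons that share libraries were set beside 20 simulations of unchanged groups. Alternatives were other scalings (RLE and upper quartile), other filters, DESeq2, limma-voom, the older quasi-likelihood method, only the libraries of the 2 groups, stricter thresholds, a replicate block and leaving out each library. Protein-coding genes alone and a crossed block were added after seeing the data. With 1 library of a group left out, the lone library is assumed to vary like the others. The WT libraries enter the comparison of OFF with ON only through the filter, the scaling and the shared estimate of the spread. A call of that comparison lost without a WT library therefore does not point to the levels in ON or OFF. Losses of a named gene's call are listed for fits that left out a library. Losses under other alternatives are named only in some cases. Scalings moved the median of all genes by at most 0.08 on the log2 scale.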

Results

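RNA was sequenced from CD4 T cells sorted from mouse spleen, in 3 groups of 2 samples. WT samples were described as mature naive cells of wild type mice, sorted as CD3+CD4+CD25-CD45RBhi. ON and OFF samples were described as immature naive cells of RBPJind mice, sorted as CD3+CD4+CD25-CD45RBint. CD45RB is a surface isoform of CD45 that was used here to grade the cells. RBPJ is the DNA-binding protein through which Notch receptors act on transcription, and in RBPJind mice it is induced by doxycycline (Dox). ON mice had Dox in their water for 4 weeks, so that their cells matured while responsive to Notch. OFF mice had Dox for 3 weeks and then none for 1 week of peripheral maturation, and the labels call these cells Notch unresponsive. All samples carry the treatment label Dox, and for WT no duration is given.

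Counts assigned to genes came to 17122640 and 17025551 in WT, 18973296 and 19319183 in ON, and 18043797 and 17200098 in OFF. Genes with a count numbered 33138 and 30592 in WT, 29456 and 28288 in ON, and 24210 and 25061 in OFF. These numbers did not follow the gene counts and did not overlap between groups, so a difference in library complexity ran along all 3 comparisons. Of 47729 genes in the table, 15780 were tested, and the biological coefficient of variation over the 6 libraries was 15.7%. The first principal component (49.96% of the variance) separated WT from both RBPJind groups, and the second (24.03%) separated ON from OFF. Medians of gene lists are log2 fold changes. The labels do not say whether the 2 samples of a group came from separate animals, so p-values measure only the spread between these samples. As a check of the sex of the animals, Xist, the RNA of the inactive X chromosome, had group means of 695 CPM in WT, 449 in ON and 894 in OFF, and the Y-linked Ddx3y, Kdm5d and Eif2s3y had 0 counts in every library, which allows up to 3 counts in each. Uty had 1 count in 1 OFF library.

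The comparison of OFF with ON asks what changed when Notch responsiveness was withdrawn for the last week of maturation. Genotype and sort gate were the same. OFF mice also had no Dox in that week, so effects of Dox itself cannot be told apart here. Rbpj (ENSMUSG00000039191; GRCm38 chromosome 5, 53466152 to 53657362) was counted at 88.9 ± 13.1 CPM in ON, 30.7 ± 1.32 in OFF and 35.7 ± 0.590 in WT (SD, n = 2). It was 2.89-fold lower in OFF than in ON (log2 fold change -1.53 ± 0.14, SE; adjusted p = 0.00195), and it was not called between OFF and WT (log2 fold change -0.22 ± 0.14; adjusted p = 0.422). Dtx1, a Notch target that encodes the ubiquitin ligase Deltex 1 (ENSMUSG00000029603; chromosome 5, 120680202 to 120711927), followed the same order, with 527 ± 50.1 CPM in ON, 169.7 ± 35.3 in OFF and 198 ± 0.126 in WT. Its fall from ON to OFF was 3.10-fold (adjusted p = 0.00234). Both calls held under every alternative run. Rbpj-ps3, a processed pseudogene of Rbpj (chromosome 6, 46529354 to 46530794) that was singled out after its values were seen, was 0.267 ± 0.130 CPM in WT, 41.5 ± 7.63 in ON and 2.22 ± 0.687 in OFF (log2 fold change of OFF against ON -4.23 ± 0.25, adjusted p = 2.92e-04). In OFF it was 8.15-fold higher than in WT (adjusted p = 0.0119), a call lost without WT 1, WT 2 or OFF 2 (adjusted p up to 0.0843) and with limma-voom (0.0726). It is near-identical in sequence to Rbpj, so the counts of both are uncertain, and a count over the whole gene cannot show whether an exon was deleted. Hes1, another Notch target, was too low to test, with a mean of 0.279 CPM in ON and 0.177 in OFF. Notch1 stood at 344 CPM in ON and 345 in OFF (adjusted p = 0.984). Of the 7 tested genes of the Notch target list, Dtx1 alone was called, and the list as a whole was not (adjusted p = 0.243).

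**Figure D1:**
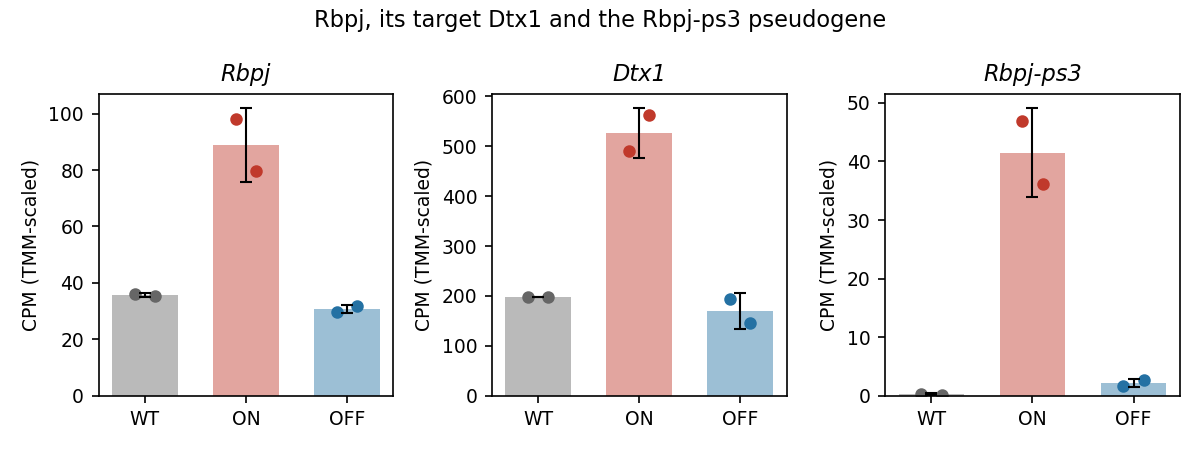
TMM-scaled CPM of Rbpj, its target Dtx1 and the processed pseudogene Rbpj-ps3 in the 3 groups. Points are single libraries, bars are group means and error bars are SD (n = 2); Rbpj was 88.9 CPM in ON against 30.7 in OFF and 35.7 in WT, and Rbpj-ps3 was 41.5 CPM in ON against 2.22 in OFF.

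Genes of effector T cells were among the named protein-coding genes lower in OFF than in ON. The memory and effector list was not called (median -0.14, adjusted p = 0.0807), with 2 of 30 members called lower and 3 adjusted over the list alone. Its direction rested on single libraries. It was higher without ON 1 (adjusted p = 0.896), called higher without OFF 1, and called lower without WT 1 (adjusted p = 0.0407), ON 2 (0.00293) or OFF 2 (9.07e-08) and with a mean CPM of at least 1 (0.0269). The chemokine gene Ccl4 fell 3.93-fold, from 19.7 ± 2.78 to 5.01 ± 2.10 CPM (adjusted p = 0.00942), and the serine protease inhibitor genes Serpina3f and Serpina3g fell 5.44-fold and 3.39-fold (adjusted p = 0.00639 and 0.00563). Further falls were those of the granzyme gene Gzmk (5.79-fold), the chemokine genes Ccl3 (4.02-fold) and Ccl5 (3.52-fold), the cytokine gene Il21 (log2 fold change -2.27), the efflux pump gene Abcb1a (3.84-fold), the transglutaminase gene Tgm2 (3.43-fold), Asb2 (3.30-fold) and Prdm16 (3.30-fold). These further falls were less secure, and the losses listed here cover only fits that left out a library. Of all 17 alternatives the calls of Gzmk and Ccl5 were each lost in 9 and that of Prdm16 in 8. The call of Gzmk was lost without WT 1, WT 2, OFF 1 or OFF 2 (adjusted p up to 0.199). The call of Ccl3 was lost without WT 1, WT 2 or ON 2 (adjusted p up to 0.173). The call of Ccl5 was lost without ON 1, ON 2, OFF 1 or OFF 2 (adjusted p up to 0.188). The call of Il21 was lost without OFF 1 (adjusted p up to 0.0914). The call of Abcb1a was lost without OFF 1 or OFF 2 (adjusted p up to 0.114). The call of Tgm2 was lost without OFF 2 (adjusted p up to 0.0532). The call of Asb2 was lost without WT 2 or OFF 1 (adjusted p up to 0.132). The call of Prdm16 was lost without WT 1, WT 2, ON 1 or OFF 1 (adjusted p up to 0.197). Except for Prdm16, all of these genes were lower in WT than in ON by group mean. For Ccl5 the means were 5.84 CPM in WT, 261 in ON and 74.3 in OFF.

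Genes that rose in OFF included Chst3, a chondroitin sulfotransferase gene, at 5.65 ± 1.48 CPM in ON and 22.3 ± 3.66 in OFF (3.94-fold, adjusted p = 0.00639), and the integrin gene Itga9 (3.44-fold, adjusted p = 0.0109). Zbtb10, a zinc finger gene, rose 3.95-fold. The call of Zbtb10 was lost without OFF 1 (adjusted p up to 0.0579). The list of quiescent naive T cell regulators rose as a group (median 0.33, adjusted p = 1.44e-05, adjusted p = 0.764 with an estimated correlation). Of its 18 tested members 1 was called (8 adjusted over the list alone): Foxo1, a transcription factor of naive T cell homeostasis, went from 189.6 ± 0.261 to 346 ± 2.29 CPM (1.83-fold, adjusted p = 0.00867). Bach2, Satb1 and Tob1 had log2 fold changes of 0.67, 0.45 and 0.69 and were not called. Genes that accompany the maturation of naive cells were also higher as a list (median 0.19, adjusted p = 6.83e-04, adjusted p = 0.764 with an estimated correlation). None of its 18 members was called by edgeR (7 adjusted over the list alone, 7 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma-voom); Cd28 was at 118 CPM in ON and 209 in OFF, and Klf2 at 179.6 and 261.

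The list of early response genes of T cell receptor signalling was also higher in OFF (median 0.30, adjusted p = 6.09e-05, adjusted p = 0.764 with an estimated correlation). Like both naive lists it kept its call with each library left out. Whether receptor signals or handling of the cells raised these genes was not tested. Of its 26 members 3 rose (11 adjusted over the list alone, with 1 lower): the AP-1 genes Fosb (2.61-fold, adjusted p = 0.00933) and Fos (1.69-fold) and the phosphatase gene Dusp2 (1.55-fold). The call of Fos was lost without WT 1, WT 2, ON 2, OFF 1 or OFF 2 (adjusted p up to 0.0834). The call of Dusp2 was lost without WT 1, WT 2, ON 2, OFF 1 or OFF 2 (adjusted p up to 0.152). In the follicular helper list (median 0.34, adjusted p = 0.0198, adjusted p = 0.876 with an estimated correlation), Il6st (1.78-fold) and Bcl6 (2.21-fold), the lineage-defining repressor, rose and Il21 fell, out of 15 tested (6 higher and 3 lower adjusted over the list alone); the list lost its call without ON 2 or OFF 2 (adjusted p up to 0.359). Among 14 genes of immature thymic and newly exported T cells, Sox4 rose 2.16-fold (median 0.27, adjusted p = 0.0412, adjusted p = 0.764 with an estimated correlation; 5 adjusted over the list alone), and the list lost its call without ON 1, ON 2 or OFF 2 (up to 0.228). The call of Il6st was lost without WT 1, WT 2 or OFF 2 (adjusted p up to 0.0647). The call of Bcl6 was lost without WT 2 or OFF 2 (adjusted p up to 0.0624). The call of Sox4 was lost without ON 1, ON 2 or OFF 2 (adjusted p up to 0.0811). The TGF-beta list was higher (median 0.28, adjusted p = 0.00264, adjusted p = 0.764 with an estimated correlation) and lost its call without ON 1 (0.0521). The sialic acid list was higher (median 0.26, adjusted p = 0.0175, adjusted p = 0.764 with an estimated correlation) and lost its call without OFF 2 (0.0814). Neither had a member called by edgeR or limma-voom (TGF-beta: 7 of 16 at an unadjusted p under 0.05, 0 by DESeq2, 0 adjusted over the list alone; sialic acid: 8 of 18, 2 and 4). The call of Il21 was lost without OFF 1 (adjusted p up to 0.0914).

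Cell division and growth genes were lower in OFF as lists, with few members called. The proliferation list (median -0.40, adjusted p = 0.00127, adjusted p = 0.895 with an estimated correlation) had 1 of 36 members called lower (2 adjusted over the list alone), the chromatin gene Hmgb2 (1.99-fold, adjusted p = 0.0491). The call of Hmgb2 was lost without WT 1, WT 2, ON 1 or OFF 1 (adjusted p up to 0.202). The list lost its call without ON 1 or OFF 1 (adjusted p up to 0.588). Respiratory chain genes (median -0.13, adjusted p = 0.00264, adjusted p = 0.876 with an estimated correlation) lost theirs without the same libraries (up to 0.457), and ribosome assembly genes (median -0.18, adjusted p = 0.00159, adjusted p = 0.876 with an estimated correlation) without ON 2 (0.170). No member of either list was called by edgeR or limma-voom (17 of 62 and 8 of 28 at an unadjusted p under 0.05, 2 and 3 by DESeq2, 5 and 5 lower adjusted over the list alone). The T helper 1 list fell (median -0.39, adjusted p = 0.00548, adjusted p = 0.876 with an estimated correlation), 3 of 14 members being called lower (3 adjusted over the list alone), the chemokine genes Ccl3, Ccl4 and Ccl5; Ifng was at 13.8 ± 5.53 CPM in ON and 6.68 ± 3.48 in OFF (adjusted p = 0.178). Its call was lost without ON 1 or OFF 1 (up to 0.394). MHC class I and antigen processing genes (median -0.15, adjusted p = 0.0485, adjusted p = 0.876 with an estimated correlation) lost their call without any library but ON 2 (up to 0.531), with no member called by edgeR or limma-voom (2 of 21 at an unadjusted p under 0.05, 1 by DESeq2, 1 lower adjusted over the list alone). The call of Ccl3 was lost without WT 1, WT 2 or ON 2 (adjusted p up to 0.173). The call of Ccl5 was lost without ON 1, ON 2, OFF 1 or OFF 2 (adjusted p up to 0.188).

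Markers of other cells moved too. The B cell list was higher in OFF (median 1.00, adjusted p = 1.49e-04, adjusted p = 0.876 with an estimated correlation) with no member called by edgeR or limma-voom (13 of 20 at an unadjusted p under 0.05, 2 by DESeq2, 9 higher and 1 lower adjusted over the list alone). Cd74 was 189 CPM in ON and 189.9 in OFF, and the list lost its call without OFF 2 (0.0850). The CD8 T cell list was lower (median -0.70, adjusted p = 0.00264, adjusted p = 0.764 with an estimated correlation; 2 of 7 called, Gzmk and Ccl5, 2 adjusted over the list alone), and lost its call without ON 1 or OFF 1 (up to 0.104). Gzmk and Ccl5 were also named above among the falls of effector genes, so the CD8 list cannot tell CD8 T cells from effector CD4 T cells. Cd8a was 5.79 CPM in ON and 3.57 in OFF. In the regulatory T cell list median and mean differed in sign (0.37 and -0.06; adjusted p = 0.919), and Foxp3, its defining gene, was 34.4 ± 5.13 CPM in ON and 57.7 ± 29.8 in OFF (adjusted p = 0.262). Median, mean and test also differed in sign for the Notch target, Notch machinery, proximal T cell receptor signalling, T helper 17, Wnt, p53, myeloid, erythroid and stromal lists, none of which was called. The call of Ccl5 was lost without ON 1, ON 2, OFF 1 or OFF 2 (adjusted p up to 0.188). The call of Gzmk was lost without WT 1, WT 2, OFF 1 or OFF 2 (adjusted p up to 0.199).

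Small nuclear and nucleolar RNAs, which guide the modification and splicing of other RNAs, were lower in ON than in both other groups. Of 209 tested, 59 were called lower in ON than in WT and 1 higher, and 35 were called higher in OFF than in ON and 0 lower (median log2 fold change 0.82). The shift was not confined to them. Other annotated genes that are neither protein coding nor pseudogenes numbered 2059, mostly long non-coding RNAs and unclassified transcripts but also short ribosomal and miscellaneous RNAs. Of these edgeR called 17 between OFF and ON, each higher in OFF (median 0.24, 66.6% above 0), and 40 higher and 148 lower in ON than in WT (median -0.39). Snora69 was 0.930 ± 0.0864 CPM in ON, 7.70 ± 1.53 in OFF and 6.82 ± 1.18 in WT (8.22-fold from ON to OFF, adjusted p = 0.00443). Snora23 rose 3.34-fold, Snord118, the U8 RNA of ribosome assembly, 3.14-fold, Snora41 4.15-fold, Snord16a 2.87-fold and Rnu12, the U12 spliceosomal RNA, 4.55-fold. The call of Rnu12 was lost without OFF 2 (adjusted p up to 0.0552). The call of Snord16a was lost without OFF 1 (adjusted p up to 0.0577). The signal recognition particle RNA gene Rn7s1 rose 3.77-fold. As a share of gene counts the class made up 0.318 ± 0.025% in ON, 0.581 ± 0.057% in OFF and 0.561 ± 0.034% in WT (SD, n = 2). Xist rose 1.99-fold (adjusted p = 0.0156), a call lost with only the 4 libraries of the comparison fitted (adjusted p = 0.0625). The share of reads that did not align was also lowest in ON, with a mean of 12.1% against 23.2% in OFF and 20.3% in WT.

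**Figure D2:**
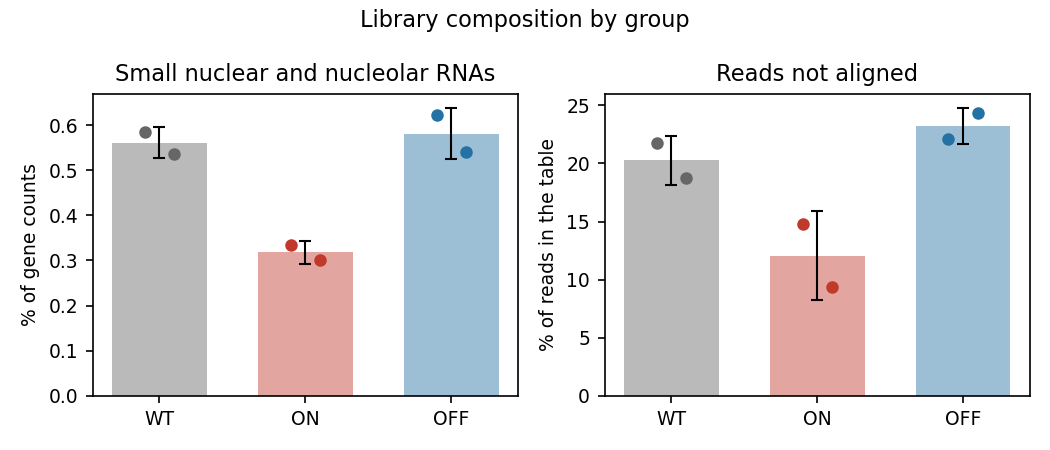
Small nuclear and nucleolar RNAs as a percent of gene counts and unaligned reads as a percent of reads in the table, by group. Points are libraries, bars are means and error bars are SD (n = 2); both shares were lowest in ON, with means of 0.318% and 12.1%.

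In all, 162 genes were called between OFF and ON, 95 higher and 67 lower in OFF (3008 at an unadjusted p under 0.05). The balance turned under some alternatives, to 249 higher and 370 lower without ON 1, 70 and 117 without ON 2, 76 and 81 with a mean CPM of at least 1, 19 and 39 with only protein-coding genes fitted and 578 and 632 with a crossed replicate block. Among protein-coding genes 41 were higher and 63 lower. The WT libraries are not part of this comparison, and leaving 1 out changes the filter, the scaling and the shared estimate of the spread. The count moved with single libraries, from 67 without WT 2 and 78 without WT 1, 80 without OFF 1 and 92 without OFF 2, to 619 without ON 1, and was 58 when only the 4 libraries of the comparison or only protein-coding genes were fitted, 99 with limma-voom and 484 with DESeq2. Of 45 lists tested, 14 were called (8 higher, 6 lower); with an estimated correlation 0 were (smallest adjusted p 0.764, 0 at an unadjusted p under 0.05), and with fry 0 (8 at an unadjusted p under 0.05), and 9 were called without ON 1.

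**Figure D3:**
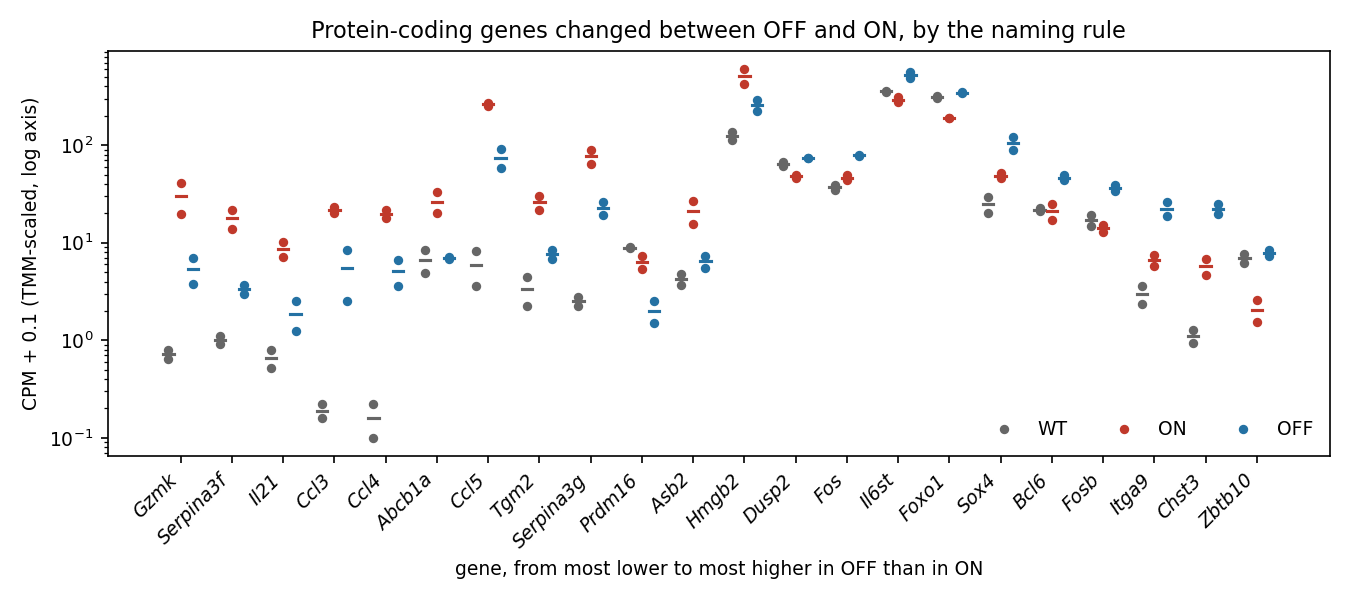
Protein-coding genes called between OFF and ON that the naming rule gave, other than Rbpj and Dtx1, with CPM plus 0.1 on a log axis. Points are libraries and short lines are group means (n = 2); genes are ordered by their change, from Gzmk (5.79-fold lower in OFF) to Zbtb10 (3.95-fold higher).

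The comparison of ON with WT sets Notch responsive RBPJind cells beside mature wild type cells. The groups differ in genotype, sort gate and maturity at once, and these cannot be told apart here. Rbpj was 2.49-fold higher in ON (log2 fold change 1.32 ± 0.14, adjusted p = 5.35e-04), and Dtx1 2.67-fold (adjusted p = 6.58e-04). The Notch target list rose (median 0.35, adjusted p = 1.85e-04, adjusted p = 0.175 with an estimated correlation), with 2 of 7 members called (4 adjusted over the list alone), Dtx1 and Il2ra, the gene of the CD25 antigen used to exclude cells in the sort. Il2ra was 4.42 ± 0.328 CPM in WT and 26.3 ± 1.96 in ON (5.93-fold). Notch1 was 288 CPM in WT and 344 in ON (adjusted p = 0.257). Cd4 was 624 and 667 CPM, and Ptprc, the CD45 gene, 1687 and 1789 CPM, with neither called.

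Genes of dividing, regulatory and effector T cells were higher in ON than in WT. These lists go against reading the ON sort as resting naive cells only. Whether naive cells or other cells of the gate carried these RNAs was not measured. The proliferation list rose (median 2.77, adjusted p = 2.19e-36, adjusted p = 0.281 with an estimated correlation), 34 of 36 members being called higher (35 adjusted over the list alone). Hmgb2 was 125 ± 17.02 CPM in WT and 513 ± 125 in ON (4.09-fold, adjusted p = 3.95e-04), and the replication licensing gene Mcm3 and the spindle gene Nusap1 were 2.57-fold and 12.1-fold higher. Replication-dependent histone genes rose with it (median 1.94, adjusted p = 1.34e-15, adjusted p = 0.334 with an estimated correlation; 17 of 23, 22 adjusted over the list alone). The regulatory T cell list rose (median 2.54, adjusted p = 5.84e-29, adjusted p = 0.175 with an estimated correlation), with 15 of 17 called (16 adjusted over the list alone): Foxp3 went from 2.56 ± 0.157 to 34.4 ± 5.13 CPM (13.4-fold, adjusted p = 0.00232), Tigit from 0.790 to 37.9 and Nrp1 5.90-fold. Tolerance and anergy genes rose (median 0.81, adjusted p = 1.52e-16, adjusted p = 0.175 with an estimated correlation; 13 higher and 1 lower of 21, 15 and 3 adjusted over the list alone), among them the inhibitory receptor genes Pdcd1 (12.03-fold, adjusted p = 3.30e-05) and Lag3 (38.9-fold).

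Memory and effector genes rose as a list (median 2.27, adjusted p = 1.01e-24, adjusted p = 0.318 with an estimated correlation), 24 of 30 members being called (25 adjusted over the list alone). The transcription factor gene Maf was 7.50-fold higher (adjusted p = 6.42e-05) and Ccl5 44.8-fold, from 5.84 ± 3.33 to 261 ± 9.76 CPM. The T helper 1 list rose (median 2.21, adjusted p = 5.44e-15, adjusted p = 0.281 with an estimated correlation), with 10 of 14 called higher and 10 adjusted over the list alone. The T helper 2 list rose (median 1.89, adjusted p = 1.64e-07, adjusted p = 0.175 with an estimated correlation), with 4 of 8 called higher and 5 adjusted over the list alone. The T helper 17 list rose (median 1.10, adjusted p = 0.00228, adjusted p = 0.342 with an estimated correlation), with 3 of 7 called higher and 3 adjusted over the list alone. The last lost its call without ON 1 (0.0555). Among their members the Th1 and cytotoxic regulator Eomes was 8.88-fold higher, Il10 56.5-fold and Batf 2.14-fold. The follicular helper list rose (median 0.67, adjusted p = 8.40e-05, adjusted p = 0.324 with an estimated correlation; 7 higher and 1 lower of 15, 9 and 2 adjusted over the list alone), Il21 being 15.1-fold higher. Several of the largest changes came from genes nearly silent in WT. Ccl4 had 2 counts in WT and 780 in ON, a ratio of 333 (95% counting interval 91.8 to 2753), and Ccl3 had 3 and 862, a ratio of 245 (83.6 to 1191). Gcg, the proglucagon gene, had 0 counts in WT and 706 in ON, at least 201-fold higher with 3 counts set as the floor over the WT group; the ON libraries held 547 and 159 of these counts. Granzyme B (Gzmb) was 1.10 ± 0.481 CPM in WT and 152 ± 105 in ON (adjusted p = 0.0183), Gzma 0.328 ± 0.382 and 15.9 ± 14.7, Gzmk 48.4-fold higher, and Penk and Lgals3 53.5-fold and 49.6-fold. Such intervals and floors cover counting error only. The call of Gcg was lost without WT 1, WT 2, OFF 1 or OFF 2 (adjusted p up to 0.254). The call of Gzma was lost without WT 1, WT 2, OFF 1 or OFF 2 (adjusted p up to 0.231). The call of Gzmb was lost without WT 1, WT 2 or OFF 2 (adjusted p up to 0.176). The call of Lgals3 was lost without WT 1 or WT 2 (adjusted p up to 0.185). The call of Penk was lost without WT 1 or WT 2 (adjusted p up to 0.0824).

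Genes of quiescent and mature naive cells were lower in ON. The naive regulator list fell (median -0.36, adjusted p = 1.85e-05, adjusted p = 0.324 with an estimated correlation), with 7 of 18 members called lower (8 adjusted over the list alone), including Foxo1 (1.63-fold), Foxp1 (1.65-fold) and the antiproliferative gene Tob1 (2.34-fold). The mature naive list fell (median -0.26, adjusted p = 3.43e-04, adjusted p = 0.281 with an estimated correlation; 7 lower and 1 higher of 18, 7 and 2 adjusted over the list alone). Dapl1 went from 43.2 ± 6.37 to 5.11 ± 2.02 CPM (8.43-fold, adjusted p = 1.05e-04), the complement regulator Cd55 was 5.36-fold lower and the interleukin 7 receptor gene Il7r 2.35-fold, whereas H2-Q6 was 2.49-fold higher. H2-Q6 belongs to a family of near-identical class I genes, so its count is uncertain. Other large falls were those of Ttc28 (7.76-fold), Arhgap29 (6.29-fold), Gprc5b (5.18-fold), Sntb1 (4.09-fold), Dse (3.99-fold), Fgf13 (3.99-fold) and Slc25a27 (3.76-fold). The heat shock list, which also responds to tissue handling, fell (median -0.82, adjusted p = 8.40e-05, adjusted p = 0.334 with an estimated correlation; 6 of 13, 7 adjusted over the list alone), with Hspa1b at 8.64 ± 5.79 CPM in WT and 0.800 ± 0.481 in ON. The call of Fgf13 was lost without WT 1, WT 2, ON 1, OFF 1 or OFF 2 (adjusted p up to 0.237). The call of Foxo1 was lost without WT 1 or WT 2 (adjusted p up to 0.0651). The call of Foxp1 was lost without WT 1 or WT 2 (adjusted p up to 0.0868). The call of Hspa1b was lost without ON 1 (adjusted p up to 0.0505). The call of Slc25a27 was lost without WT 1, WT 2 or ON 1 (adjusted p up to 0.155).

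Lists of signalling, survival and migration genes were higher in ON. Early T cell receptor response genes rose (median 0.25, adjusted p = 4.27e-04, adjusted p = 0.342 with an estimated correlation), with 10 higher and 1 lower of 26 called and 11 higher and 1 lower adjusted over the list alone. Irf4 was 4.31-fold, Dusp4 10.7-fold and Nr4a1 1.88-fold higher. Cytokine receptor and JAK-STAT genes rose (median 0.26, adjusted p = 2.77e-04, adjusted p = 0.175 with an estimated correlation), with 8 higher and 1 lower of 24 called and 9 higher and 3 lower adjusted over the list alone. The feedback inhibitor Cish was 2.53-fold higher. NF-kB targets rose (median 0.33, adjusted p = 1.54e-04, adjusted p = 0.288 with an estimated correlation), with 9 of 21 called higher and 10 higher and 1 lower adjusted over the list alone. The survival and apoptosis list rose (median 0.19, adjusted p = 0.00197, adjusted p = 0.198 with an estimated correlation; 10 higher, 1 lower of 25; 11 and 4 adjusted over the list alone), its members of smallest p including the pro-death gene Pmaip1 (12.04-fold) and the pro-survival gene Bcl2a1d (7.25-fold). The migration list rose (median 0.79, adjusted p = 0.00228, adjusted p = 0.342 with an estimated correlation; 12 higher, 3 lower of 24; 14 and 4 adjusted over the list alone) and lost its call without ON 2 (0.0671); the integrin gene Itgal was 2.01-fold higher and Cxcr4 3.12-fold lower. The call of Nr4a1 was lost without WT 2 (adjusted p up to 0.0579).

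Respiratory chain genes rose (median 0.33, adjusted p = 1.52e-05, adjusted p = 0.470 with an estimated correlation), with 16 of 62 called higher and 19 adjusted over the list alone. Glycolysis genes rose (median 0.39, adjusted p = 0.00158, adjusted p = 0.342 with an estimated correlation), with 7 higher and 1 lower of 19 called and 11 higher and 1 lower adjusted over the list alone. Unfolded protein response genes rose (median 0.36, adjusted p = 0.00340, adjusted p = 0.324 with an estimated correlation), with 6 of 21 called higher and 6 adjusted over the list alone. MHC class I and antigen processing genes rose (median 0.27, adjusted p = 4.27e-04, adjusted p = 0.342 with an estimated correlation), with 5 of 21 called higher and 7 higher and 1 lower adjusted over the list alone. Cox5b was 1.94-fold, the glucose transporter gene Slc2a3 1.67-fold, Hk2 4.02-fold, Canx 1.61-fold and Psmb8 1.57-fold higher. The call of Canx was lost without WT 1 or WT 2 (adjusted p up to 0.128). The call of Cox5b was lost without WT 2 (adjusted p up to 0.0603). The call of Hk2 was lost without WT 2 (adjusted p up to 0.101). The call of Psmb8 was lost without WT 1 or WT 2 (adjusted p up to 0.104). The call of Slc2a3 was lost without WT 1 or WT 2 (adjusted p up to 0.104).

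Markers of other cell types were also higher in ON. The MHC class II genes counted in the B cell list were among the most significant: H2-Ab1 was 10.4 ± 1.83 CPM in WT and 102 ± 13.1 in ON (9.77-fold, adjusted p = 2.44e-05), and Cd74 7.22-fold. The B cell list (median 1.85, adjusted p = 5.47e-16, adjusted p = 0.281 with an estimated correlation) had 10 of 20 members higher and 1 lower (11 and 1 adjusted over the list alone), and Ighm fell 1.40-fold. Dendritic cell markers rose (median 2.22, adjusted p = 2.81e-17, adjusted p = 0.175 with an estimated correlation), with 10 of 14 called higher and 11 adjusted over the list alone. CD8 T cell markers rose (median 3.15, adjusted p = 5.90e-10, adjusted p = 0.175 with an estimated correlation), with 5 of 7 called higher and 5 higher and 1 lower adjusted over the list alone. Of these 7 markers 5 also stood in another list, among them Eomes and Ccl5 in the T helper 1 list. The list therefore cannot tell CD8 T cells from effector CD4 T cells. Natural killer and innate lymphoid markers rose (median 1.90, adjusted p = 4.82e-07, adjusted p = 0.324 with an estimated correlation), with 6 of 10 called higher and 7 adjusted over the list alone. Myeloid markers rose (median 0.76, adjusted p = 0.00742, adjusted p = 0.396 with an estimated correlation), with 6 of 18 called higher and 7 higher and 1 lower adjusted over the list alone. Itgax was at 2.51 CPM in WT and 17.5 in ON, Cd8a at 0.849 and 5.79, Nkg7 at 1.63 and 53.1 and Mpeg1 at 2.57 and 12.9. Plasma cell and erythroid markers were not called as lists, and Jchain was 0.117 CPM in WT and 1.80 in ON. The call of Ighm was lost without WT 1, WT 2 or ON 2 (adjusted p up to 0.247). The call of Jchain was lost without WT 1 or WT 2 (adjusted p up to 0.118). The call of Mpeg1 was lost without WT 1 or WT 2 (adjusted p up to 0.0920).

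Between ON and WT 2342 genes were called, 1527 higher and 815 lower in ON, and with upper quartile scaling 2363, 1272 higher and 1091 lower. Small nuclear and nucleolar RNAs gave 1 higher and 59 lower of 209. Of the named genes 108 were called, and 43 of these calls were lost without WT 1, 48 without WT 2 and 9 without ON 1. Leaving out a WT library reduced the count, to 494 without WT 1 and 368 without WT 2. Of 45 lists 27 were called (24 higher, 3 lower), 0 with an estimated correlation (smallest adjusted p 0.175, 8 at an unadjusted p under 0.05) and 13 with fry. Median, mean and test differed in sign for the sialic acid, interferon, Wnt, p53 and mitochondrial RNA lists, none of which was called.

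The comparison of OFF with WT sets RBPJind cells that the labels call Notch unresponsive beside the same wild type cells. It again joins genotype, gate and maturity, and the response of the cells to Notch was not measured. Rbpj was 30.7 CPM in OFF and 35.7 in WT, and Dtx1 169.7 and 198 (adjusted p = 0.457). The Notch target list was higher in OFF (median 0.34, adjusted p = 0.00203, adjusted p = 0.160 with an estimated correlation), with 2 of 7 called (3 adjusted over the list alone): Il2ra (6.11-fold, adjusted p = 1.73e-04) and Gata3 (1.40-fold, adjusted p = 0.0471). Il2ra also stands in the regulatory T cell and cytokine lists, and Gata3 in the T helper 2 list. With Dtx1 not called, the rise of this list cannot be read as a response to Notch. The call of Gata3 was lost without WT 1, WT 2 or OFF 2 (adjusted p up to 0.338).

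Regulatory and tolerance genes were higher in OFF than in WT. The regulatory T cell list (median 2.61, adjusted p = 1.87e-37, adjusted p = 0.160 with an estimated correlation) had 14 of 17 members higher (16 adjusted over the list alone). Foxp3 was 2.56 ± 0.157 CPM in WT and 57.7 ± 29.8 in OFF (22.4-fold, adjusted p = 0.00168), Ikzf2, the Helios gene, 7.41 and 163 CPM (adjusted p = 0.00450), and Lrrc32 14.99-fold higher. Of 21 tolerance and anergy genes 15 rose (median 1.29, adjusted p = 9.45e-28, adjusted p = 0.160 with an estimated correlation; 17 higher and 1 lower adjusted over the list alone), with Lag3 28.6-fold and Pdcd1 8.48-fold higher. The follicular helper list rose (median 1.12, adjusted p = 2.48e-12, adjusted p = 0.160 with an estimated correlation; 8 of 15, 13 higher and 1 lower adjusted over the list alone): Cd200 was 3.29-fold, the chemokine receptor gene Cxcr5 4.69-fold and Izumo1r 2.17-fold higher. Early T cell receptor response genes rose (median 0.52, adjusted p = 4.89e-15, adjusted p = 0.160 with an estimated correlation; 11 of 26, 15 adjusted over the list alone), with Nr4a1 at 37.2 ± 1.45 CPM in WT, 70.1 ± 7.65 in ON and 104 ± 9.18 in OFF. Immature thymic genes rose as a list (median 0.80, adjusted p = 1.01e-04, adjusted p = 0.160 with an estimated correlation; 7 of 14, 7 higher and 1 lower adjusted over the list alone); Sox4 was 4.26-fold and Tox 2.48-fold higher, and Cd24a, a maturation marker, 1.29 ± 0.391 CPM in WT and 9.78 ± 6.31 in OFF (adjusted p = 0.0217). In ON against WT that list was not called (adjusted p = 0.101). The call of Cd24a was lost without WT 1 or WT 2 (adjusted p up to 0.207). The call of Ikzf2 was lost without WT 1 or WT 2 (adjusted p up to 0.139).

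Division and effector genes were higher in OFF than in WT as well. The same caution about reading the sort as naive cells only holds for OFF. The proliferation list (median 2.39, adjusted p = 1.49e-33, adjusted p = 0.238 with an estimated correlation) had 22 of 36 members called (34 adjusted over the list alone), Top2a going from 33.4 ± 4.09 to 221 ± 65.5 CPM (6.63-fold). Histone genes rose (median 1.69, adjusted p = 2.86e-16, adjusted p = 0.305 with an estimated correlation), with 7 of 23 called higher and 22 adjusted over the list alone. Memory and effector genes rose (median 2.24, adjusted p = 9.21e-27, adjusted p = 0.238 with an estimated correlation), with 18 of 30 called higher and 27 adjusted over the list alone. The T helper 1 list rose (median 1.99, adjusted p = 2.60e-13, adjusted p = 0.238 with an estimated correlation), with 8 of 14 called higher and 10 adjusted over the list alone. The T helper 2 list rose (median 1.89, adjusted p = 5.19e-07, adjusted p = 0.160 with an estimated correlation), with 6 of 8 called higher and 6 adjusted over the list alone. The T helper 17 list rose (median 1.05, adjusted p = 0.00202, adjusted p = 0.308 with an estimated correlation), with 2 of 7 called higher and 4 adjusted over the list alone. The last lost its call without OFF 2 (0.0561). Maf was 3.27-fold higher, Eomes 6.92-fold, Ccl5 12.7-fold and Il1rl1, the ST2 gene, 15.6-fold. Ccl4 had 2 counts in WT and 169 in OFF, a ratio of 84.4 (95% counting interval 23.01 to 703), Ccl3 3 and 182, a ratio of 60.6 (20.4 to 297), and Gcg 0 and 95, at least 31.6-fold higher by the same floor but not called (adjusted p = 0.198). Fgl2 was 0.739 ± 0.223 CPM in WT and 33.99 ± 18.98 in OFF, and Chst3 22.1-fold higher. The call of Ccl3 was lost without WT 1 or WT 2 (adjusted p up to 0.153). The call of Fgl2 was lost without WT 1, WT 2 or OFF 2 (adjusted p up to 0.197). The call of Il1rl1 was lost without WT 1 or WT 2 (adjusted p up to 0.0788).

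The largest falls in OFF by the naming rule were those of Prdm16 (4.64-fold), Arhgap29 (4.22-fold), Dapl1 (4.13-fold), Tspan9 (3.80-fold), Ttc28 (3.44-fold), Pde8a (3.12-fold), Cd55 (3.11-fold), Ntrk3 (2.87-fold), Ksr2 (2.75-fold) and Stx1a (2.63-fold). The mature naive list was not called (adjusted p = 0.237, median 0.10 but mean -0.09), and neither was the naive regulator list (adjusted p = 0.297). Foxo1 was 346 CPM in OFF and 309.7 in WT. Heat shock genes fell (median -0.66, adjusted p = 4.11e-08, adjusted p = 0.238 with an estimated correlation; 5 of 13, 10 adjusted over the list alone), Hspa1b from 8.64 to 0.445 CPM. Ribosomal protein genes were lower as a list (median -0.12, adjusted p = 0.00497, adjusted p = 0.567 with an estimated correlation) with no member called by edgeR, DESeq2 or limma-voom (3 of 78 at an unadjusted p under 0.05, 0 lower adjusted over the list alone), and the list lost its call without WT 1 or OFF 1 (up to 0.212). The call of Hspa1b was lost without OFF 1 or OFF 2 (adjusted p up to 0.139). The call of Ksr2 was lost without WT 1 or WT 2 (adjusted p up to 0.0819). The call of Pde8a was lost without WT 1 or WT 2 (adjusted p up to 0.0773). The call of Stx1a was lost without WT 1, WT 2 or OFF 2 (adjusted p up to 0.123). The call of Tspan9 was lost without WT 2 (adjusted p up to 0.0662).

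Signalling, survival, migration and metabolic lists were also higher in OFF. Cytokine receptor and JAK-STAT genes rose (median 0.30, adjusted p = 6.74e-07, adjusted p = 0.160 with an estimated correlation), with 8 higher and 1 lower of 24 called and 10 higher and 1 lower adjusted over the list alone. Survival and apoptosis genes rose (median 0.20, adjusted p = 0.00410, adjusted p = 0.160 with an estimated correlation), with 3 of 25 called higher and 6 adjusted over the list alone. Migration genes rose (median 0.53, adjusted p = 7.16e-05, adjusted p = 0.300 with an estimated correlation), with 11 higher and 1 lower of 24 called and 14 higher and 2 lower adjusted over the list alone. NF-kB targets rose (median 0.27, adjusted p = 2.19e-04, adjusted p = 0.238 with an estimated correlation), with 4 of 21 called higher and 9 adjusted over the list alone. Sterol synthesis genes rose (median 0.31, adjusted p = 0.00506, adjusted p = 0.461 with an estimated correlation), with 3 of 23 called higher and 5 adjusted over the list alone. Unfolded protein response genes rose (median 0.34, adjusted p = 0.00506, adjusted p = 0.305 with an estimated correlation), with 1 of 21 called higher and 2 adjusted over the list alone. Pmaip1 was 6.89-fold, Tnfrsf1b 2.35-fold, Sqle 1.88-fold and Pdia6 1.44-fold higher. MHC class I and antigen processing genes rose (median 0.16, adjusted p = 0.0319, adjusted p = 0.551 with an estimated correlation), with 2 of 21 called higher and 2 adjusted over the list alone. Glycolysis genes rose (median 0.33, adjusted p = 0.0203, adjusted p = 0.461 with an estimated correlation), with 1 higher and 1 lower of 19 called and 5 higher and 1 lower adjusted over the list alone. Respiratory chain genes rose as a list (median 0.15, adjusted p = 0.0236, adjusted p = 0.690 with an estimated correlation). None of its members was called by edgeR, DESeq2 or limma-voom, 10 of 62 had an unadjusted p under 0.05, and 0 were higher adjusted over the list alone. These last 3 lists each depended on 1 library. Their calls were lost, in this order, without WT 1, OFF 2 and OFF 2 (adjusted p 0.361, 0.0736 and 0.364). The call of Pdia6 was lost without WT 1, WT 2 or OFF 2 (adjusted p up to 0.311). The call of Sqle was lost without WT 1, WT 2 or OFF 2 (adjusted p up to 0.216). The call of Tnfrsf1b was lost without WT 1 or WT 2 (adjusted p up to 0.0580).

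Markers of other cells were higher in OFF than in WT. The B cell list (median 2.41, adjusted p = 1.21e-36, adjusted p = 0.160 with an estimated correlation) had 18 of 20 members higher (19 adjusted over the list alone), with Cd74 at 26.1 ± 5.36 CPM in WT and 189.9 ± 25.1 in OFF, and Ighm at 186 and 192 (adjusted p = 0.865). Dendritic cell markers rose (median 2.28, adjusted p = 4.64e-28, adjusted p = 0.139 with an estimated correlation), with 9 of 14 called higher and 12 adjusted over the list alone. CD8 T cell markers rose (median 2.79, adjusted p = 7.69e-08, adjusted p = 0.160 with an estimated correlation), with 4 of 7 called higher and 4 adjusted over the list alone. As above, this list shares members with the effector lists. Natural killer and innate lymphoid markers rose (median 2.12, adjusted p = 9.99e-09, adjusted p = 0.238 with an estimated correlation), with 5 of 10 called higher and 6 adjusted over the list alone. Myeloid markers rose (median 0.95, adjusted p = 0.00202, adjusted p = 0.379 with an estimated correlation), with 2 of 18 called higher and 6 higher and 3 lower adjusted over the list alone. Mpeg1 went from 2.57 ± 0.177 to 35.1 ± 2.27 CPM, and Tcf4 was 3.67-fold higher.

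**Figure D4:**
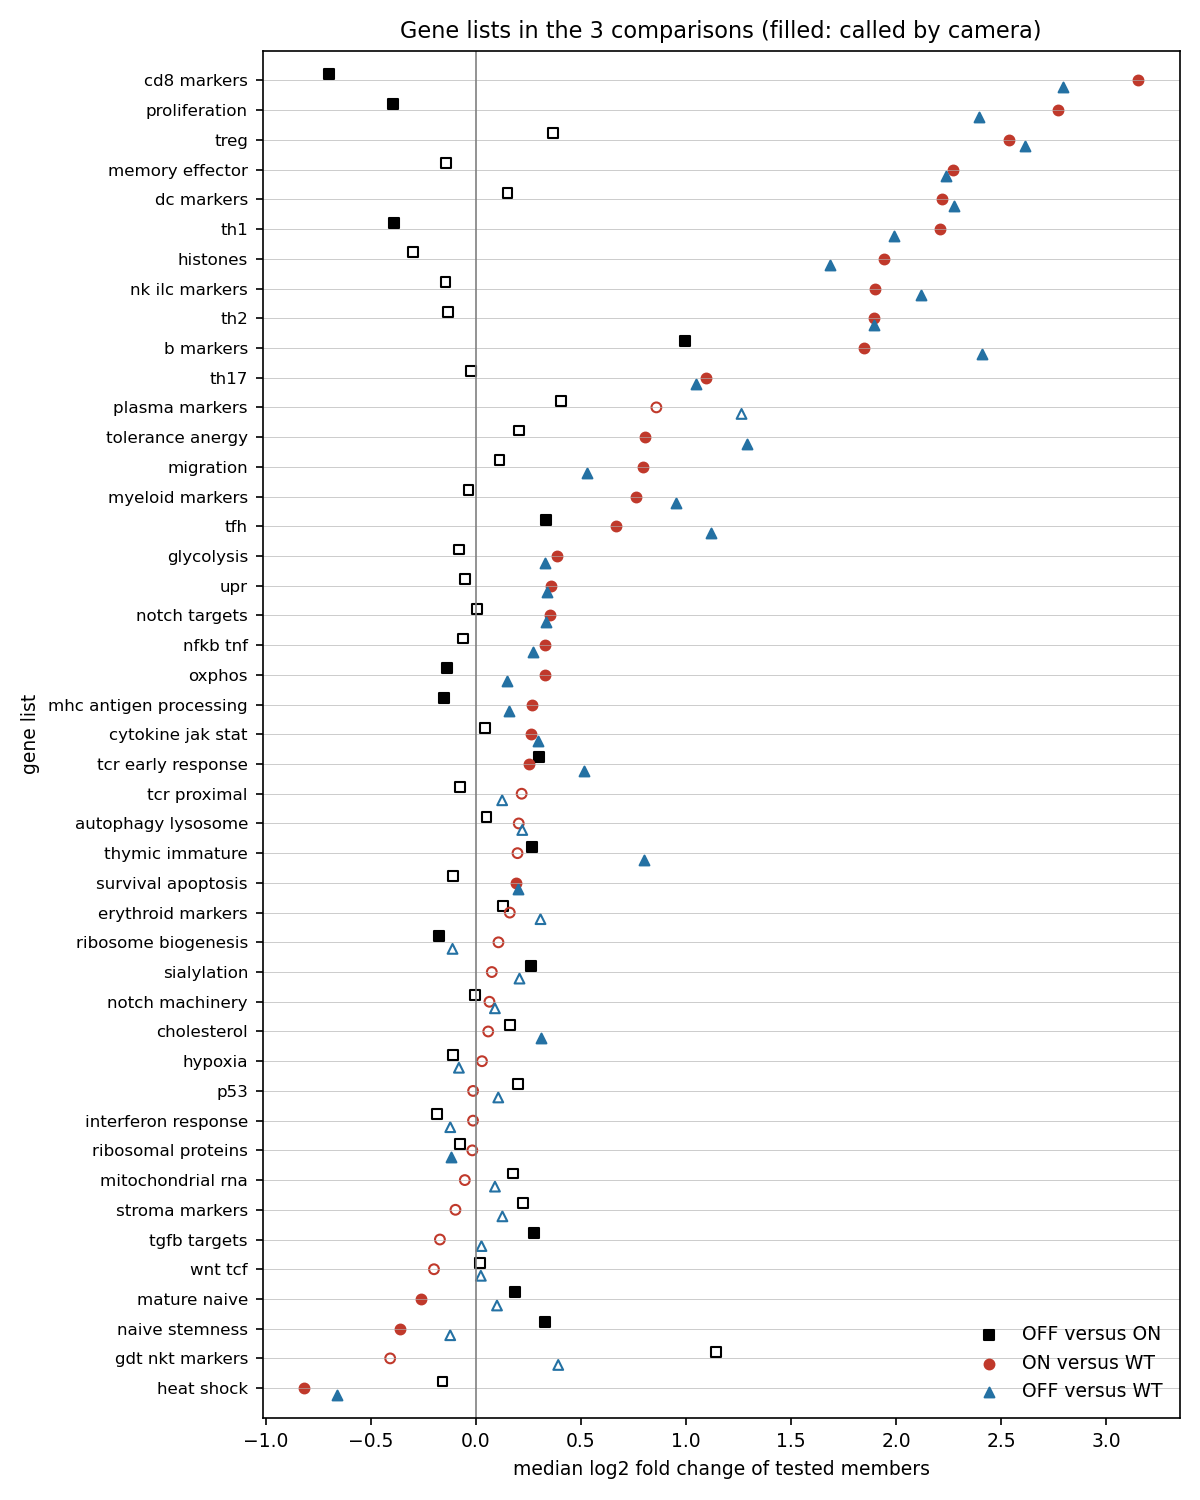
Median log2 fold change of the tested members of each of the 45 gene lists in the 3 comparisons. Squares are OFF versus ON, circles ON versus WT and triangles OFF versus WT, and filled symbols were called by camera with the preset correlation; the naive regulator list lay at 0.33, -0.36 and -0.12 in that order.

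In total 1078 genes were called between OFF and WT, 741 higher and 337 lower in OFF. Of the named genes 93 were called, and 45 of these calls were lost without WT 1, 47 without WT 2 and 29 without OFF 2. The count was 223 without WT 1, 224 without WT 2 and 340 without OFF 2, and 571 with limma-voom. Of 45 lists 28 were called (26 higher, 2 lower), 0 with an estimated correlation (smallest adjusted p 0.139, 12 at an unadjusted p under 0.05) and 14 with fry. Median, mean and test differed in sign for the mature naive, hypoxia, erythroid and stromal lists, none of which was called. Whether ON and OFF differ in their distance from WT for a given gene is answered only by the direct comparison of OFF with ON.

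The calls against WT overlapped. ON and OFF shared 584 genes higher and 123 lower than WT, 707 in all, where independent lists of these sizes would share 71.7 and 17.4, and 2 genes were called in opposite directions. In 20 simulations with no changed gene, in which the WT libraries were simulated too, the overlap was 0.25 genes on average and 2 at most. With no gene changed few calls can arise, so these simulations cannot show what shared WT libraries add to the overlap of real calls. The 2 WT libraries are too few to split, so part of the excess may come from the shared controls. The overlap was 171 without WT 1, 140 without WT 2 and 298 without OFF 2. Of the 162 genes called between OFF and ON, 121 moved from their ON level in the direction of WT, 9 moved away and 32 were not called between ON and WT. Protein-coding genes made up 72 of the 121 and small nuclear or nucleolar RNAs 33. Because both comparisons use the ON libraries, these counts lean toward WT by chance alone. Across the 15780 genes, which are not independent replicates, the covariance of the OFF minus ON and WT minus ON log2 fold changes was 0.172, against 0.0720 in simulated unchanged groups (Pearson's r 0.254 against 0.483). The difference of 0.0996 was smaller than its SD of 0.120 over the fits that left out a library: it was -0.00132 without WT 2, -0.0216 without OFF 1 and 0.262 without ON 2. A general shift of OFF cells along the axis from ON to WT was therefore not resolved.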

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

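The tests of a short RNA yield, of the scaling, of the 4 cell mixtures behind the effector genes and of a fixed share of Rbpj reads were chosen after the result was seen. Ambiguous reads were a mean of 1.18% of reads in OFF, above the WT mean of 1.03%, with no overlap of libraries. Unaligned reads were a mean of 23.2% in OFF against 20.3% in WT, again above both WT libraries.

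Rbpj-ps3 had 0.743 counts per 100 Rbpj counts in WT, 46.7 in ON and 7.19 in OFF. A fixed share of Rbpj reads placed on the pseudogene would keep that ratio, but it was 62.8 times higher in ON than in WT (95% interval 33.0 to 138, which covers counting error only). By library it was 45.4 and 47.8 in ON and 0.494 and 0.993 in WT. Transcription of the surrounding Cntnap2 gene was argued against by its level, at most 1.14 CPM in any library, that one a WT library, and at most 0.511 in ON. The pseudogene was 99.7% identical to an Rbpj transcript over all of its 1441 bases, so reads of an induced Rbpj copy that resembles it are a candidate source. This stays a hypothesis, since no reads or construct sequence were used.

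Small nuclear and nucleolar RNAs were higher in OFF than in ON. Transcription of their host genes was argued against for the 25 of 35 called RNAs that had a tested host. These 25 host genes had a median log2 fold change of -0.0919 (95% interval -0.21 to 0.15). The 35 RNAs, picked as called, had 1.74 and all 209 tested had 0.82. The other called RNAs are not covered, and host gene counts stand in for host transcription. TMM adds the log2 ratio of the ON to the OFF factors to every gene alike, and that ratio was at most 0.124 over the 4 pairs of libraries, so TMM alone is not the cause. A lower yield of short RNAs in ON cannot be told apart, because the test set mixed classes: 337 other short genes had a median of 0.30 (0.21 to 0.38), under the 0.41 set as the bound, but 36 ribosomal and miscellaneous RNA genes, picked after the classes were seen, had 0.98 (0.66 to 1.33). The shift was not confined to small nuclear and nucleolar RNAs. The 2059 other genes that are neither protein coding nor pseudogenes had a median of 0.24, and the 17 called were higher in OFF. They hold those of the short genes that are not pseudogenes, and the called ones include Rn7s1, Rmrp, Terc and n-R5s115. The called ones also include a long RNA, Xist (log2 fold change 0.99), whose call was lost with only the 4 libraries of the comparison fitted. No median without the short genes was taken, so how far longer RNAs shifted as a group is not shown. The intervals resample genes and do not cover the spread between libraries. Notch responsiveness stays open as an untested explanation.

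Ccl3, Ccl4, Ccl5, Il10, Il21 and Maf are the members of the memory, T helper and follicular helper lists that were called lower in OFF than in ON. Their median log2 fold change of -1.99 is set by that choice, and all 66 tested members of these lists had a median of -0.07. Il10 fell by 2.54 (adjusted p = 0.00639) and Maf by 1.20 (adjusted p = 0.0210; lost without WT 2 or OFF 1, up to 0.0579) on the log2 scale. The falls of Ccl3, Ccl5 and Il21 were also lost without single libraries, Ccl3 without WT 1, WT 2 or ON 2 (up to 0.173), Ccl5 without ON 1, ON 2, OFF 1 or OFF 2 (up to 0.188) and Il21 without OFF 1 (0.0914).

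Fewer antigen-experienced, dividing, regulatory or CD8 T cells in OFF cannot be told apart as explanations of these falls, because the bound differs with the median it is taken from. The 24 memory and effector genes higher in ON than in WT had a median of -0.39 (95% interval -0.58 to -0.00249). They were picked as higher in the same ON libraries, so their median leans lower in OFF by selection. They also include Ccl5 and Maf, 2 of the genes to be explained. The 36 proliferation genes had -0.40 (-0.46 to -0.33), 17 regulatory genes 0.37 (-0.46 to 0.67) and the 6 CD8 T cell markers other than Ccl5 -0.53 (-2.28 to 0.25). These intervals resample genes as if independent and do not cover the spread between libraries. Cd8b1 was 15.2 CPM in ON and 12.5 in OFF. The sort took CD25- CD4+ cells, but how many regulatory or CD8 T cells passed was not measured. Of 17 regulatory list genes 15 were called higher in ON than in WT and 14 in OFF than in WT. Of 7 CD8 T cell markers these counts were 5 and 4. Of the 30 memory, 36 proliferation, 17 regulatory and 7 CD8 genes, 13, 0, 8 and 5 stood in another list and 29, 36, 17 and 7 were counted in WT. Notch responsiveness itself stays open as an untested explanation.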

How the results depend on the processing

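Protein-coding genes alone and the crossed block were chosen after seeing the data. Of 349 named gene results 236 were called, 112 kept their call under every alternative, 123 lost it without some library, and 0 called genes turned sign. Between OFF and ON the 162 called genes became 58 with protein-coding genes only and 58 with the 4 libraries of the comparison, 99 with limma-voom, 484 with DESeq2, 38 at an adjusted p under 0.01, 104 with a log2 fold change of at least 1, and 67 to 619 with a library left out. Between ON and WT 2342 became 758 at 0.01, 1199 with the fold limit and 368 to 2397 with a library left out. Between OFF and WT 1078 became 571 with limma-voom, 298 at 0.01 and 223 to 1602. The 707 genes shared against WT became 140 to 930 with a library left out. Called lists were 0, 0 and 0 with an estimated correlation and 0, 13 and 14 with fry, and 9 to 17 between OFF and ON with a library left out. The change along the axis went from -0.0216 to 0.262 with a library left out; its alternatives used 5 simulations. The cause was not tested, except that smaller samples and fewer genes are part of some of these settings. Depth limits genes of few counts such as Hes1. Some named calls lost without a library were also lost under other alternatives. Of 17 alternatives Hmgb2 between OFF and ON lost its call in 12, Dusp2 between OFF and ON in 10 and Gata3 between OFF and WT in 9.

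The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.0771 for WT and ON, -0.212 for WT and OFF and -0.198 for ON and OFF. With the number as a replicate block the calls were 60, 1441 and 663, and the shared genes 460. With OFF numbers crossed as a block they were 1210, 3755 and 2082.

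Genes that were not called and lay near 0 turned sign, and the cause was not tested. Log2 fold changes are given with the main value in brackets, then each alternative; blocks refer to the replicate pairing. For OFF versus ON, Notch1 (0.00671): -0.00566 RLE, -0.0259 mean CPM, -0.00742 protein coding, -0.00715 4 libraries, left out -0.0888 to 0.0872, then Ptprc (0.0569): left out -0.0709 to 0.169, then Cd44 (0.254): left out -0.0710 to 0.518, then Il7r (0.183): left out -0.0269 to 0.423, then Il2ra (0.0436): left out -0.0732 to 0.147, then H2-Q7 (-0.0928): left out -0.253 to 0.0415, then Cd4 (0.0176): -0.0149 mean CPM, left out -0.0593 to 0.0847, then Trdc (0.0763): left out -0.143 to 0.322, then Ctss (-0.0824): left out -0.182 to 0.0211, then Mmp9 (0.330): left out -0.320 to 1.46, then Cd74 (0.00977): -0.00191 RLE, -0.0228 mean CPM, -0.00462 protein coding, -0.00377 4 libraries, left out -0.151 to 0.151, then Bpgm (0.146): left out -0.0801 to 0.341, then Itgb3 (0.217): left out -0.00888 to 0.480. For ON versus WT, Mmp9 (-0.299): left out -1.40 to 1.48, then Itgb3 (-0.217): left out -0.468 to 0.0366, then Pecam1 (-0.133): left out -0.287 to 0.0492. For OFF versus WT, Ighm (0.0528): -0.0240 upper quartile, -0.00132 mean CPM, left out -0.0593 to 0.183, then Mmp9 (0.0309): -0.0453 upper quartile, -0.0241 mean CPM, -0.0130 protein coding, -0.0135 4 libraries, left out -0.725 to 1.82, then Itgb3 (2.17e-04): -0.0206 RLE, -0.0746 upper quartile, -0.0550 mean CPM, -0.0454 protein coding, -0.0121 crossed replicate block, -0.0440 4 libraries, -0.00734 limma-voom, left out -0.127 to 0.137.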

Other observations

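Ptprc, Cd44 and H2-Q7, fixed as genes of sorting or maturity, were not called between OFF and ON. A count over the whole Ptprc gene cannot show the CD45RB isoform used in the sort. Ptprc was also not called between ON and WT, which came from different CD45RB gates. These counts therefore do not show whether the ON and OFF gates matched. Ptprc was 1789 ± 169 CPM in ON and 1861 ± 189.9 in OFF, Cd44 66.8 ± 3.45 and 79.7 ± 21.5, and H2-Q7 368 ± 4.34 and 345 ± 54.9 (SD, n = 2), with adjusted p of 0.851, 0.527 and 0.753. Notch3 stood at 1.01 CPM in WT, 0.549 in ON and 1.27 in OFF.

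Gcg counts were uneven within groups: 547 and 159 in the ON libraries, 19 and 76 in the OFF libraries and 0 in both WT libraries. MHC class II transcripts were higher in both RBPJind groups than in WT, with Cd74 at 26.1 CPM in WT, 189 in ON and 189.9 in OFF.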
